A study of Mus musculus with 2 samples.

How the data were processed

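Chromatin immunoprecipitation with sequencing (ChIP-seq) for histone H3 acetylated at lysine 27 (H3K27ac), a mark found at active promoters and enhancers, was measured in mouse intestine at embryonic day 14.5. The series has 1 group of 2 biological replicates, which per the labels were separate pools of intestines, from 24 embryos for replicate 1 and 34 embryos for replicate 2, with both sexes mixed. The authors deposited 4 peak lists on mm10: 1 per replicate, 1 called on both replicates together (the pooled list), and 1 that, per the notes deposited beside the lists, was derived from both replicates' lists and the pooled list (the replicated list). Every replicated peak was identical in position and name to a pooled peak. The aligner, the peak caller, its version and its thresholds are not given in the sources used here.

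For each peak the authors deposited a fold enrichment over the control, which is a linear ratio that belongs to that peak in that list. The authors also deposited the −log10 of a p-value and of a q-value for each peak, and the position of its summit. The fold enrichment was used here only to describe, rank and filter peaks within a list, since its level can differ between lists for reasons other than acetylation. Orders of named genes are those of the replicated list unless another is named, and can differ in each replicate's own list. The lowest −log10 p was 2.04 in each replicate's list and 2.02 in the pooled and replicated lists, so the deposited lists hold peaks down to a lenient threshold. Read depth per replicate is not given in the sources used here and is unknown, so no interval for counting reads could be made; 2 replicates also limit the precision. A single group allows no comparison between conditions.

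Peaks were analysed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plotted with matplotlib 3.10.9. Genes were the 21853 protein-coding genes of GENCODE M21 on the 21 assembled chromosomes of GRCm38, the assembly behind mm10; 0 peaks extended past a chromosome end, and the 7 or 8 peaks per list on unplaced sequence were left out of everything but the peak counts. A promoter was 1 kb on each side of the transcription start site (TSS) of any protein-coding transcript, and a gene was marked if a peak overlapped its promoter by at least 1 bp. The promoter fold enrichment of a gene is the highest of any peak at any of its TSSs. It can therefore come from a TSS that lies near the promoter of a neighbouring gene. A distal peak overlapped no promoter. Promoters of noncoding genes were not set aside, so peaks at them count as distal. Distal peaks were counted for a gene if their midpoint lay within 50 kb of any of its TSSs, so that 1 peak can count for several neighbouring genes. Location was assigned by peak midpoint, in the order promoter, exon, intron, intergenic, and compared with 100 random placements on the same chromosomes outside assembly gaps; overlap between replicates used the same placements.

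Gene lists, motifs, tests and the rule for named genes were fixed before the data were examined. The 23 lists are those of the plot of gene lists; the silent genes are odorant and vomeronasal receptor genes, and a gene in more than 1 list counts in each. The symbol Cblif was matched through its older symbol Gif, and all other symbols matched directly. Promoter marking was tested with a two-sided Fisher's exact test against all other protein-coding genes, with exact (Clopper-Pearson) 95% intervals for shares of genes, and the mean number of distal peaks per gene with a two-sided permutation test of gene labels (100000 resamples, smallest possible p 1e-05). Both were adjusted by Benjamini-Hochberg over the 23 lists, at 0.05. Genes are not independent replicates, so these p-values describe the marking in these 2 pools. Named genes are, per list, the 4 marked members with the highest fold enrichment, up to 4 members in alphabetical order with no promoter peak in any list, and up to 3 members in alphabetical order with a promoter peak in 1 replicate alone; also all Hox genes, the 10 top stitched regions, the 10 genes with most distal peaks and the 10 strongest promoter peaks.

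Distal replicated peaks were joined over gaps of up to 10 kb into stitched regions and ranked by the sum of fold enrichment times width; the nearest TSS is given as a position, not as a target. Motifs were searched as consensus sequences on both strands: HNF4 (CAAAGTCCA), CDX (TTTATKG), GATA (AGATAA), FOXA (TGTTTAC), AP-1 (TGASTCA), SRF CArG box (CCWWWWWWGG), SOX (ACAAAGG), TEAD (GGAATG), FOXF (TRTTTRY), PHOX2 (TAATYNRATTA), ETS (ACCGGAAGT), E-box (CANNTG), MEF2 (CTAWWWATAG), TCF/LEF (CTTTGAW) and CTCF (CCASYAGRKGGC), with 1 mismatch allowed for HNF4, ETS and CTCF. The sequences of HNF4, AP-1 and CDX read backwards, without complementing, served as 3 controls. Site density was compared with 100 sets of control windows matched for chromosome, width and GC content within 2 percentage points, drawn outside every peak list in up to 300 tries per window; 91.9% of the 27701 distal replicated peaks found a match in every set and were used.

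Chosen after the differences between replicates had been seen, promoters marked in 1 replicate alone were compared with 100000 draws of genes from the same decile of fold enrichment. Distal peaks in 1 replicate alone were compared with the share given by their decile of fold enrichment, against random gene lists of the same size. The random lists had the same number of genes, not of peaks. Because the difference is summed over peaks, a list with many peaks leaves their range more easily. Both were run for the 23 lists in each direction, two-sided, and adjusted over the 23 lists.

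Promoter marking, distal counts, overlap, stitching and the motif search were run on simulated data. Random placements, permutations within quintiles and the comparisons of promoters and peaks in 1 replicate alone were not. The simulated lists were adjusted over more lists than the real ones, and distal counts used fewer resamples. Of 50 simulated lists of 18 genes made higher in marking, 98.0% were called, as were 100% of those made lower and 1 of 100 unchanged lists; of 50 lists given more distal peaks, 62.0% were called, against 0 of 150 others. A simulated overlap of 39.5% was recovered as 39.5%, 400 planted motif sites as 400, and 1001 stitched regions as 1001. Alternatives tried were a q-value of 0.01 or less, a fold enrichment of 4 or more, stricter overlap, equal list sizes, each replicate's own list, the pooled list, promoter windows of 500 bp and 2 kb, the most 5' TSS, other backgrounds, distances of 20 and 100 kb, nearest TSS, gaps of 5 and 20 kb, ranking by the length covered by peaks, and 200 bp on each side of the summit.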

Results

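H3K27ac was mapped in embryonic day 14.5 mouse intestine, a stage at which the gut tube consists of an endodermal epithelium that is forming villi, a surrounding mesenchyme with differentiating smooth muscle, and a neural crest-derived enteric nervous system. The data are 2 biological replicates of 1 group, a pool of 24 embryos (replicate 1) and a pool of 34 embryos (replicate 2). Their design asks where the mark lies in this tissue and how far independent pools give the same regions. Replicate 1 had 86144 peaks covering 47.1 Mb and replicate 2 had 56744 peaks covering 28.0 Mb. The pooled list had 83901 peaks over 52.0 Mb, and the replicated list, used below unless another is named, had 41353 peaks over 40.1 Mb. Replicated peaks had a median width of 712 bp and a median fold enrichment of 4.89, as given by the authors. Read depth is unknown, and no value below carries an error from read counts.

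The strongest acetylation was shared by both pools, and the weak peaks often were not. In the top quintile of fold enrichment, 94.7% of replicate 1 peaks overlapped a replicate 2 peak, and 99.7% of replicate 2 peaks overlapped a replicate 1 peak. In the lowest quintile these shares were 17.1% and 59.3%. Over all peaks, 42.9% of replicate 1 peaks and 75.5% of replicate 2 peaks were shared, against 2.22% and 3.74% when peaks were placed at random (highest of 100 placements, 2.37% and 3.99%). Promoter peaks were shared more often than distal ones, 70.9% against 34.9% in replicate 1 and 91.9% against 68.6% in replicate 2. The order also held within the top quintile of replicate 1, with 97.3% of promoter and 91.5% of distal peaks shared. Across the 32715 replicated peaks that overlapped a peak of both replicates, Spearman's rho of the 2 fold enrichments was 0.698 (promoter 0.812, distal 0.522), a description across peaks, which are not independent replicates. Where 50% of the length of both peaks had to overlap, the share of replicate 2 peaks was 35.6%.

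**Figure D1:**
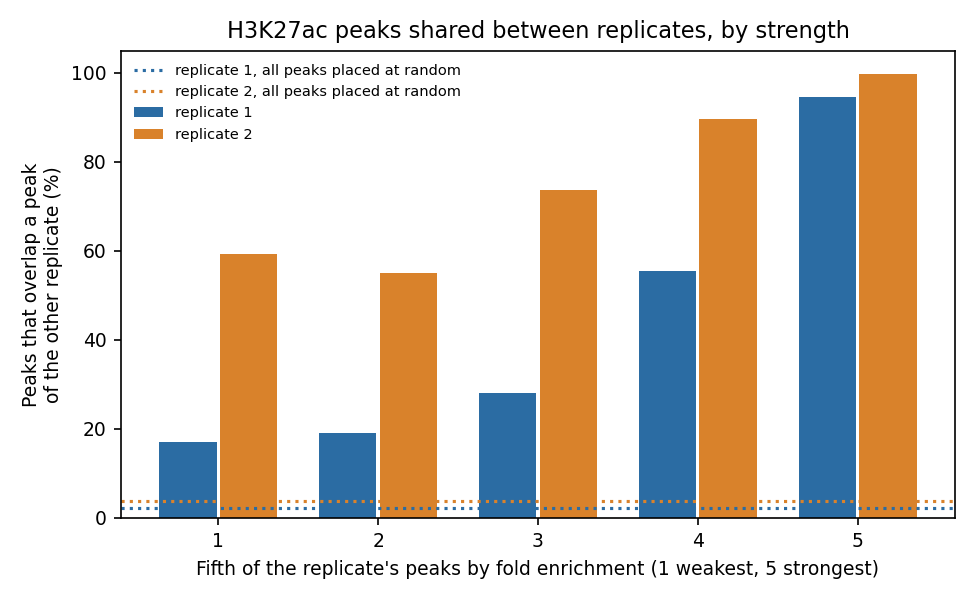
Share of each replicate's peaks (%) that overlap a peak of the other replicate by at least 1 bp, by quintile of the replicate's own fold enrichment; dotted lines give the mean over 100 random placements of all peaks. The share is 94.7% and 99.7% in the strongest quintile and 17.1% and 59.3% in the weakest.

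The replicated list kept 49.3% of the pooled peaks, with 99.9% of the top quintile and 6.94% of the lowest, and 74.3% of promoter peaks against 42.3% of distal peaks. Within quintiles the promoter and distal shares were close, 88.8% and 85.4% in the fourth and 43.2% and 38.9% in the third, so most of that gap goes with peak strength. Of its peaks on assembled chromosomes, 79.1% overlapped a peak of both replicates by at least 1 bp. A further 17.7% overlapped a peak of replicate 1 alone, 2.63% a peak of replicate 2 alone, and 0.522% (216 peaks) a peak of neither. Support by both replicates was lower under a stricter rule. In 43.8% (18097 peaks), a single peak of each replicate covered at least as much of the replicated peak as it left uncovered. Marked promoters were therefore also counted in each replicate's own list.

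Replicated peaks were concentrated at promoters. Their midpoints lay at promoters in 31.3%, against 2.67% for random placement, an 11.7-fold ratio. Introns held 36% (random 37.2%), exons 2.23% (random 2.55%) and intergenic sequence 30.4% (random 57.5%). The 13645 promoter-overlapping peaks had a median fold enrichment of 7.60 and the 27701 distal peaks 4.34. The promoter share was lower in replicate 1's own list (21%) and in the pooled list (20.6%), which hold more weak distal peaks.

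The highest promoter enrichments were spread over genes of different functions. Klf7, a Krüppel-like transcription factor gene, had the highest value, 70.5, in a peak on chromosome 1 from 64118371 to 64123151. Arrdc3 followed with 63.2, then Erbin (61.3), Zc3h4 (60.9), Gpr19 (60.4), Tnrc18 (59.2), Tsc22d1 (58.5), Pcbp1, an RNA-binding protein gene (56.4), a 10588 bp peak over the promoter of Setd1b (55.2), and Ywhaz, a 14-3-3 protein gene (55.1). The Setd1b peak also reached the edge of the promoter window of the neighbouring gene Rhof, whose own promoter peaks in replicates 1 and 2 had 5.59 and 3.89. The order of these peaks differed in replicate 1, where Klf7 (65.8) lay below Arrdc3 and Gpr19 (66.5 each) and Zc3h4 had 31.1. In replicate 2 Klf7 led them with 44.8. Of 21853 protein-coding genes, 11252 (51.5%) had a marked promoter, with 12379 in replicate 1 and 11010 in replicate 2. Both replicates marked 10765, replicate 1 alone 1614 and replicate 2 alone 245.

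Genes that set endodermal and epithelial identity were marked almost throughout. Of the endoderm transcription factors, 16 of 18 had a marked promoter (88.9%, 95% interval 65.3 to 98.6%), led by Gata6 (fold enrichment 18.5), Foxa1 (11.0), Cdx2, the factor that sets intestinal identity (10.2), and Elf3 (8.87). Of the general epithelial genes, 17 of 18 were marked (94.4%, 72.7 to 99.9%), led by the tight junction genes Cldn7 (16.6) and Cldn3 (12.1), the adhesion gene Epcam (13.8) and Grhl2 (10.9). The unmarked members were Cdx1 and Creb3l3 among the first and Ovol2 among the second, and none of these had a promoter peak in any list. Cdx1 (chromosome 18, 61018862 to 61036199) still had 4 distal replicated peaks within 50 kb. Fisher's exact test against other coding genes, of which 51.5% were marked, gave an adjusted p of 0.00325 for the endoderm factors and 0.000613 for the epithelial genes. Foxa3 and St14 had a promoter peak in replicate 1 and not in replicate 2. Within quintiles of promoter GC content the endoderm call was lost, with a permutation adjusted p of 0.106 (range over 11 alternatives 0.00160 to 0.106), and the epithelial list still passed.

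Secretory cell genes lay below other coding genes in promoter marking, and enterocyte genes did not pass the test. Of 18 enterocyte genes 5 were marked (27.8%, 9.69 to 53.5%), and Mttp, which loads lipid onto apolipoprotein B, stood far above the others at 35.7. The Mttp value was not traced to a single TSS, so a peak at the promoter of a neighbouring gene cannot be excluded. Fabp2, a fatty acid-binding protein gene, had 5.11, Dgat1 3.76 and Apob 2.64, the last 2 with a promoter peak in replicate 1 and not in replicate 2. Ace2, Apoa4, Fabp1 and Lct, the lactase gene, had no promoter peak in any list. The list did not pass Fisher's exact test (adjusted p 0.0736), and the replicates differed, with 10 members marked in replicate 1 and 2 in replicate 2. Alpi, Anpep and Apoa1 were also among the 8 marked in replicate 1 alone. In replicate 2's own list the share was 11.1%, below other genes (Fisher's exact adjusted p 0.00170, range over 11 alternatives 0.00170 to 1.00, of which 5 passed). Of 18 genes of secretory and enteroendocrine cells only Sct (3.87) and Chgb (3.62) were marked (11.1%, 1.38 to 34.7%; Fisher's exact adjusted p 0.00155), Sct in replicate 1 and not in replicate 2. Atoh1, the determinant of secretory fate, Cck, Chga and Clca1 had no promoter peak in any list. In replicate 1's own list 6 secretory members were marked, Agr2, Fcgbp and Gfi1 among them, and the call was lost (Fisher's exact adjusted p 0.0815, range over 11 alternatives 6.71e-05 to 0.0815).

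Genes of the gut mesenchyme and of smooth muscle were marked at nearly every promoter listed, in equal number in both pools. The labels name intestine and no sorted cells, so a marked promoter in any list does not show which cells carry the mark. Of the gut mesenchyme and Hedgehog target genes 19 of 20 were marked (95%, 75.1 to 99.9%), all 19 in each replicate. Col3a1, a fibrillar collagen gene, had 28.3, Ptch1, the Hedgehog receptor, 26.0, Foxf1 24.4 and Pdgfra 22.1. In replicate 1 Ptch1 (39.6) lay above Col3a1 (23.2), and in replicate 2 they were close (17.1 and 17.2). The Ptch1 promoter lay under a peak of 20381 bp and the Foxf1 promoter under a peak of 12979 bp. Barx1, a gene of stomach mesenchyme, had no promoter peak in any list. Of the smooth muscle genes 17 of 18 were marked (94.4%, 72.7 to 99.9%), all 17 in each replicate. In the replicated list Srf (22.1), Acta2, smooth muscle actin (18.4), Myl9 (18.1) and Tpm1 (17.4) led. In replicate 1 Srf had 13.3, below Myl9 (22.5), Acta2 (17.0) and Tpm1 (16.2). Only Pcp4l1 had no promoter peak in any list. Fisher's exact test gave an adjusted p of 0.000347 for the mesenchyme and 0.000613 for smooth muscle, and no alternative ended either call.

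Signalling genes of the gut were marked in 19 of 22 cases (86.4%, 65.1 to 97.1%; Fisher's exact adjusted p 0.00241). Fgfr2 had 37.5, the Notch ligand gene Jag1 35.5, the Hedgehog signal transducer Smo 27.9 and Tgfbr2 26.2, whereas Rspo2 and Wnt11 had no promoter peak in any list. Bmp2 and Wnt4 had one in replicate 1 and not in replicate 2. As annotated, Fgfr2 spans chromosome 7 from 130162451 to 133123350. Its value of 37.5 was not traced to a single TSS, so it may come from a promoter far from the gene's other TSSs. The signalling call was lost within quintiles of promoter GC content (permutation adjusted p 0.189, range over 11 alternatives 0.000981 to 0.189). Intestinal stem cell genes and Wnt targets were split, with 10 of 18 marked (55.6%, 30.8 to 78.5%; Fisher's exact adjusted p 0.853). Axin2 (30.0), Lgr4 (23.6), Myc (22.2) and Ephb2 (18.3) were strongly marked, and Lgr5, the marker of adult crypt stem cells, Lef1, Notum and Olfm4 had no promoter peak in any list. Ascl2 and Smoc2 had one in replicate 1 alone. The lead of Axin2 did not hold in both replicates. Axin2 had 48.4 in replicate 1 but 9.76 in replicate 2, there below Lgr4 (17.9), Myc (14.4) and Ephb2 (10.6).

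The lists of enteric nerves, endothelium, mesothelium and blood did not pass the test of promoter marking, which in lists of this size does not show that they equal other genes. The enteric nervous system list had 11 of 21 members marked (52.4%, 29.8 to 74.3%; Fisher's exact adjusted p 1.00). Hand2, also a gene of gut mesenchyme, had 20.5, the endothelin receptor gene Ednrb 11.1, Erbb3 10.2 and the neuronal RNA-binding protein gene Elavl4 8.94. Nos1, Phox2a, Plp1 and S100b had no promoter peak in any list. Foxd3 and Gfra2 were among the 4 members with one in replicate 1 alone, and Prph was the only member with one in replicate 2 alone. Endothelium had 10 of 18 members marked, with Fli1 at 10.9, Pecam1 at 8.63, Prox1 at 4.86 and Egfl7 at 4.48, no promoter peak for Flt4, and a Fisher's exact adjusted p of 0.853. Cdh5 and Cldn5 were among the 4 endothelial members with a promoter peak in replicate 1 alone, and Lyve1 among the 2 in replicate 2 alone. In the pooled list 94.4% of the endothelial promoters had a peak and the list rose above other genes (Fisher's exact adjusted p 0.00327, range over 11 alternatives 0.00327 to 1.00). Mesothelium had 4 of 12 (33.3%, 9.92 to 65.1%), led by Bnc2 (17.7), ahead of Aldh1a2 (4.68), Bnc1 (3.98) and Upk3b (3.78), while Gpm6a, Msln, Rspo1 and Tbx18 had no promoter peak in any list. Wt1 was marked in replicate 1 alone and Muc16 in replicate 2 alone. Blood and immune cells had 7 of 18 (38.9%, 17.3 to 64.3%), with the erythroid factor Klf1 at 7.45, Cx3cr1 at 5.96, Fcer1g at 4.90 and Tal1 at 4.79, Spi1 in replicate 1 alone, and no promoter peak for Alas2, Csf1r, Gata1 or Gypa. The Fisher's exact adjusted p was 0.308 for mesothelium, which passed as lower only with a fold enrichment of 4 or more (0.0487, range over 11 alternatives 0.0487 to 1.00), and 0.401 for blood.

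In the replicated list, genes of other organs lay below other coding genes in all 9 lists of them, but lung, kidney, skeletal muscle and limb and face did not pass in replicate 1's own list, and pancreas and liver did not in replicate 2's. Stomach and esophagus had 3 of 18 marked (16.7%, 3.58 to 41.4%), Pitx1 (8.51), Sox2 (3.19) and Capn8 (2.18, without a peak in replicate 2), and Atp4a, Atp4b, Gif and Gkn1 had no promoter peak. Lung had 2 of 14, Etv5 (9.0) and Abca3 (2.59, without a peak in replicate 2), and Cldn18, Lamp3, Napsa and Nkx2-1 had none. Pancreas had 3 of 18, Cela1 (6.70), Mafb (6.6) and Pnliprp1 (5.75), and liver 4 of 18, Apoh (7.22), Nr1h4 (5.83), Trf (5.40) and Ttr (4.68). The value of Apoh, annotated on chromosome 11 from 108343354 to 108414396, was not traced to a single TSS either. Amy2a5, Cel, Ctrb1 and Gcg of the pancreas and Afp, Ahsg, Alb and Apoa2 of the liver had no promoter peak. Fisher's exact adjusted p was 0.00631 for stomach and for pancreas, 0.00989 for lung and 0.0247 for liver.

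Outside the endoderm, kidney had 2 of 15 marked, Eya1 (9.77) and Sall1 (4.90), and the central nervous system 2 of 20, Dlx1 (5.91) and Dlx2 (3.83). Heart had 1 of 15, Myl3 (9.05), skeletal muscle 3 of 15, Tnni2 (9.37), Mylpf (9.15) and Tnnt3 (4.15), and limb and face 3 of 15, Satb2 (9.43), Sall4 (7.91) and Hand1 (7.33). In replicates 1 and 2 Hand1 (12.5 and 9.31) lay above Satb2 (8.37 and 6.21) and Sall4 (8.78 and 5.82). Fisher's exact adjusted p was 0.00631 for kidney, 0.000613 for the central nervous system, 0.00123 for heart and 0.0247 for skeletal muscle and for limb and face. Cited1, Emx2, Actn2, Ckm and Alx1 were among the members with no promoter peak in any list. All 20 housekeeping genes were marked, led by Ywhaz (55.1), Actb (37.2), Eef1a1 (30.0) and Polr2a (27.7), with a Fisher's exact adjusted p of 2.55e-05. Of 1465 odorant and vomeronasal receptor genes 3 were marked (0.205%, 0.0423 to 0.597%). In replicate 1's own list the lung, kidney, skeletal muscle and limb lists no longer passed (Fisher's exact adjusted p 0.237 and, for each of the last 3, 0.0510), and in replicate 2's own list pancreas (0.209) and liver (0.0833) did not. Liver also did not pass within quintiles of promoter GC content, in the pooled list or with a promoter window of 2 kb, nor did lung in the pooled list or pancreas with that window. Over 11 alternatives the adjusted p ranged from 0.00207 to 0.237 for lung, 0.00127 to 0.209 for pancreas, 0.0106 to 1.00 for liver, 0.00127 to 0.0510 for kidney, 0.00191 to 0.0510 for skeletal muscle and 0.00124 to 0.0510 for limb and face (Fisher's exact test, or permutation within GC quintiles).

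**Figure D2:**
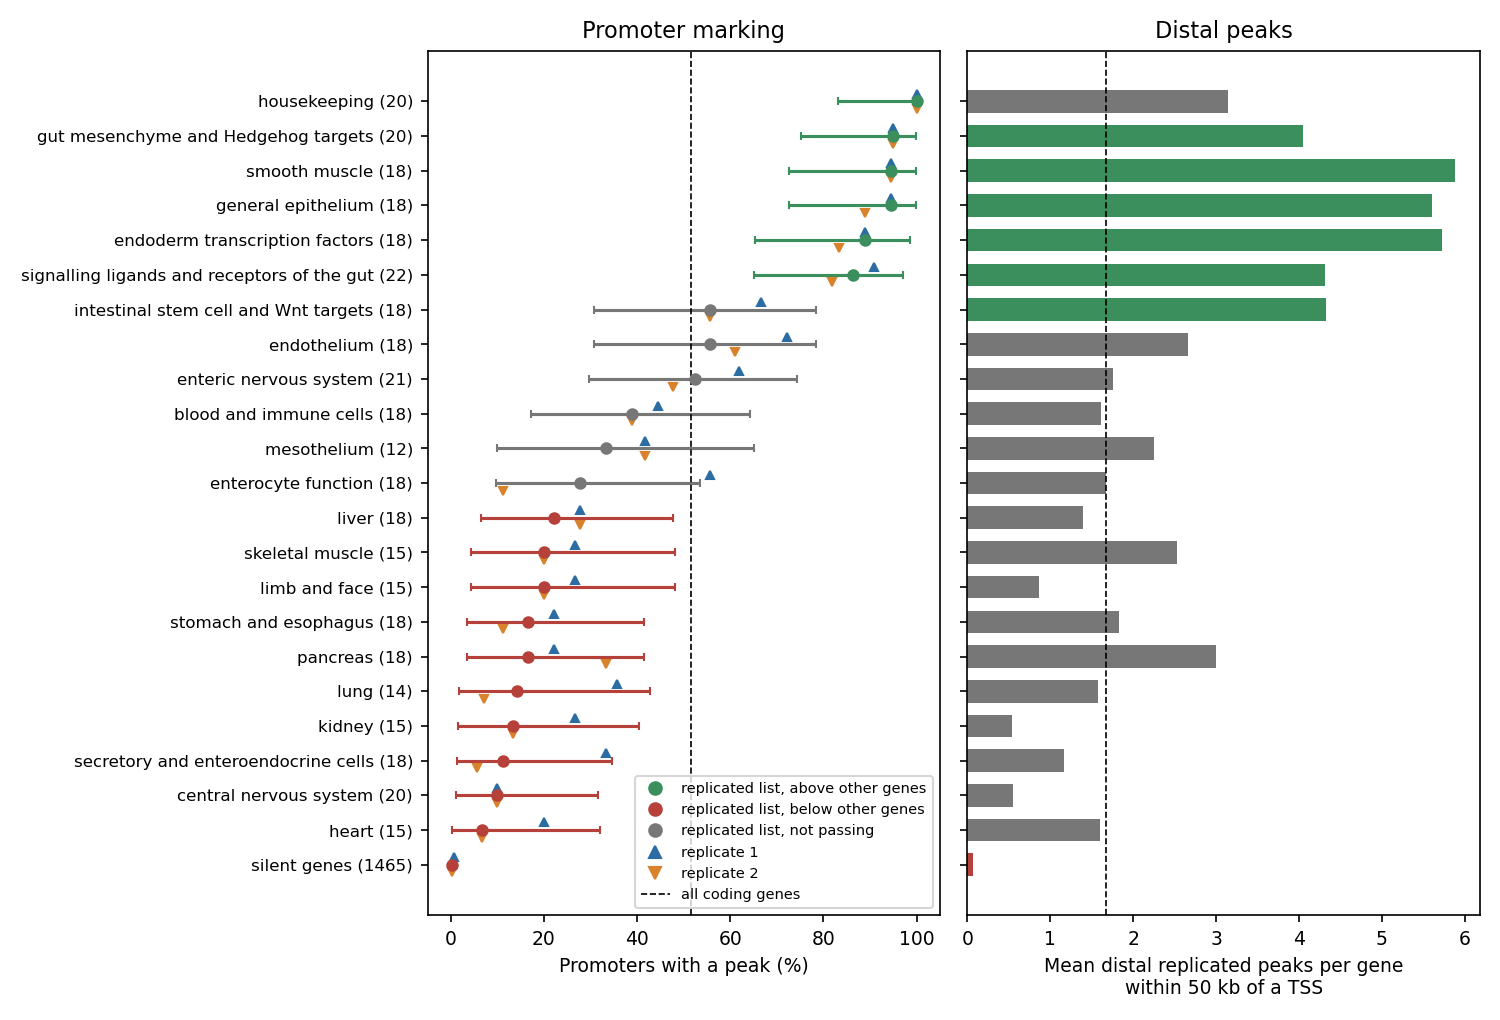
Left, share of each list's promoters with a peak (%) in the replicated list, with exact 95% intervals, and in each replicate's own list (triangles); right, mean number of distal replicated peaks per gene within 50 kb; list sizes in brackets, dashed lines all coding genes, colours by adjusted p at 0.05. Mesenchyme, smooth muscle, epithelium, endoderm factors, signalling and housekeeping genes lie above the 51.5% of all genes, and other organs below it.

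Distal peaks were more numerous around 6 lists. Smooth muscle genes had a mean of 5.89 distal replicated peaks within 50 kb, endoderm transcription factors 5.72, general epithelial genes 5.61, stem cell and Wnt targets 4.33, signalling genes 4.32 and mesenchymal genes 4.05, against 1.66 for other genes. Of the members named above, Foxa1 had 13, Tpm1 12, Elf3 11, Ptch1 11 and Ephb2 9. These are examples and not the highest counts in the lists, since Gata4, named here after its value was seen, had 17. The permutation test gave an adjusted p of 0.000115 for smooth muscle, whose unadjusted p of 1e-05 is the smallest it can give, 0.000403 for both the endoderm and the epithelial list, 0.00129 for signalling, 0.00525 for stem cell and Wnt targets and 0.00555 for mesenchyme. These 6 lists passed in both replicates and under every alternative run. Silent genes had fewer, 0.0717 per gene (permutation adjusted p 0.000115, from an unadjusted p of 1e-05).

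The remaining lists did not pass. Housekeeping genes had a mean of 3.15 (permutation adjusted p 0.0581, passing in 7 of 12 alternatives), pancreas 3.0 (0.0930), endothelium 2.67, skeletal muscle 2.53, mesothelium 2.25, stomach 1.83, enteric nervous system 1.76, enterocytes 1.67, blood 1.61, heart 1.60, lung 1.57, liver 1.39, secretory cells 1.17, limb and face 0.867, central nervous system 0.550 and kidney 0.533. Pancreas and skeletal muscle passed as higher within 100 kb (permutation adjusted p 0.0276 and 0.0136) and endothelium in the pooled list (0.0473). Within 50 kb, 9 of 15 skeletal muscle genes had no distal peak and Tnnt3 alone had 24, so that mean rests largely on Tnnt3. Among the 18 pancreas genes 6 had none. How far the calls within 100 kb rest on single genes was not tested. Cpa1, a pancreatic enzyme gene whose promoter had a peak in replicate 1 alone, had 17. Among all coding genes Foxp1 had the most, 41, then Rbpms (40), Gse1 (37), Mrpl23 (32), Rbfox2 (28), Tns1 (27), Rere (26) and Dock9, Frmd4a and Sept9 (25 each). In replicate 2's own list Rbpms (61) and Gse1 (53) had more than Foxp1 (46). Foxp1 spans chromosome 6 from 98925338 to 99522721 and has several TSSs, which widens the window in which its peaks were counted.

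The Hox clusters were acetylated mostly in their central and 3' parts and less at their 5' ends, whose genes are expressed most posteriorly in the embryo, although Hoxb1 and Hoxd1 at 3' ends were unmarked too. Of 39 Hox genes 30 had a marked promoter, 10 of 12 in paralogue groups 1 to 4, 14 of 15 in groups 5 to 9 and 6 of 12 in groups 10 to 13. All 11 Hoxa genes were marked, with promoter fold enrichments in the replicated list from 2.98 (Hoxa13) to 19.6 (Hoxa4), while in replicate 1 Hoxa2 (22.5) and Hoxa1 (20.1) were above Hoxa4 (17.1). In Hoxb the genes Hoxb2 to Hoxb9 were marked, with 33.8 for a peak shared by Hoxb3, Hoxb4 and Hoxb5, and Hoxb1 and Hoxb13 were not. Hoxc4, Hoxc5, Hoxc6, Hoxc8 and Hoxc10 were marked, and Hoxc9, Hoxc11, Hoxc12 and Hoxc13 were not. Hoxd3, Hoxd4, Hoxd8, Hoxd9, Hoxd10 and Hoxd11 were marked, and Hoxd1, Hoxd12 and Hoxd13 were not, although Hoxd13 had a peak in replicate 2 (3.10). Replicated peaks covered 62.8% of the Hoxa cluster (chromosome 6, 52155590 to 52260880), 39.8% of Hoxd (chromosome 2, 74668310 to 74765142), 38.8% of Hoxb (chromosome 11, 96194316 to 96368256) and 17.7% of Hoxc (chromosome 15, 102921103 to 103036852). The Hoxb span includes the stretch between Hoxb13, which ends at 96197447, and Hoxb9, which starts at 96271457. That stretch held no replicated peak, the first lying at 96271607. The Hoxb share is lowered by it and does not show that the part from Hoxb9 to Hoxb1 was less covered than Hoxa. Replicate 2's own peaks covered less, 19.0% for Hoxd against 38.2% in replicate 1. These are values with no test.

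**Figure D3:**
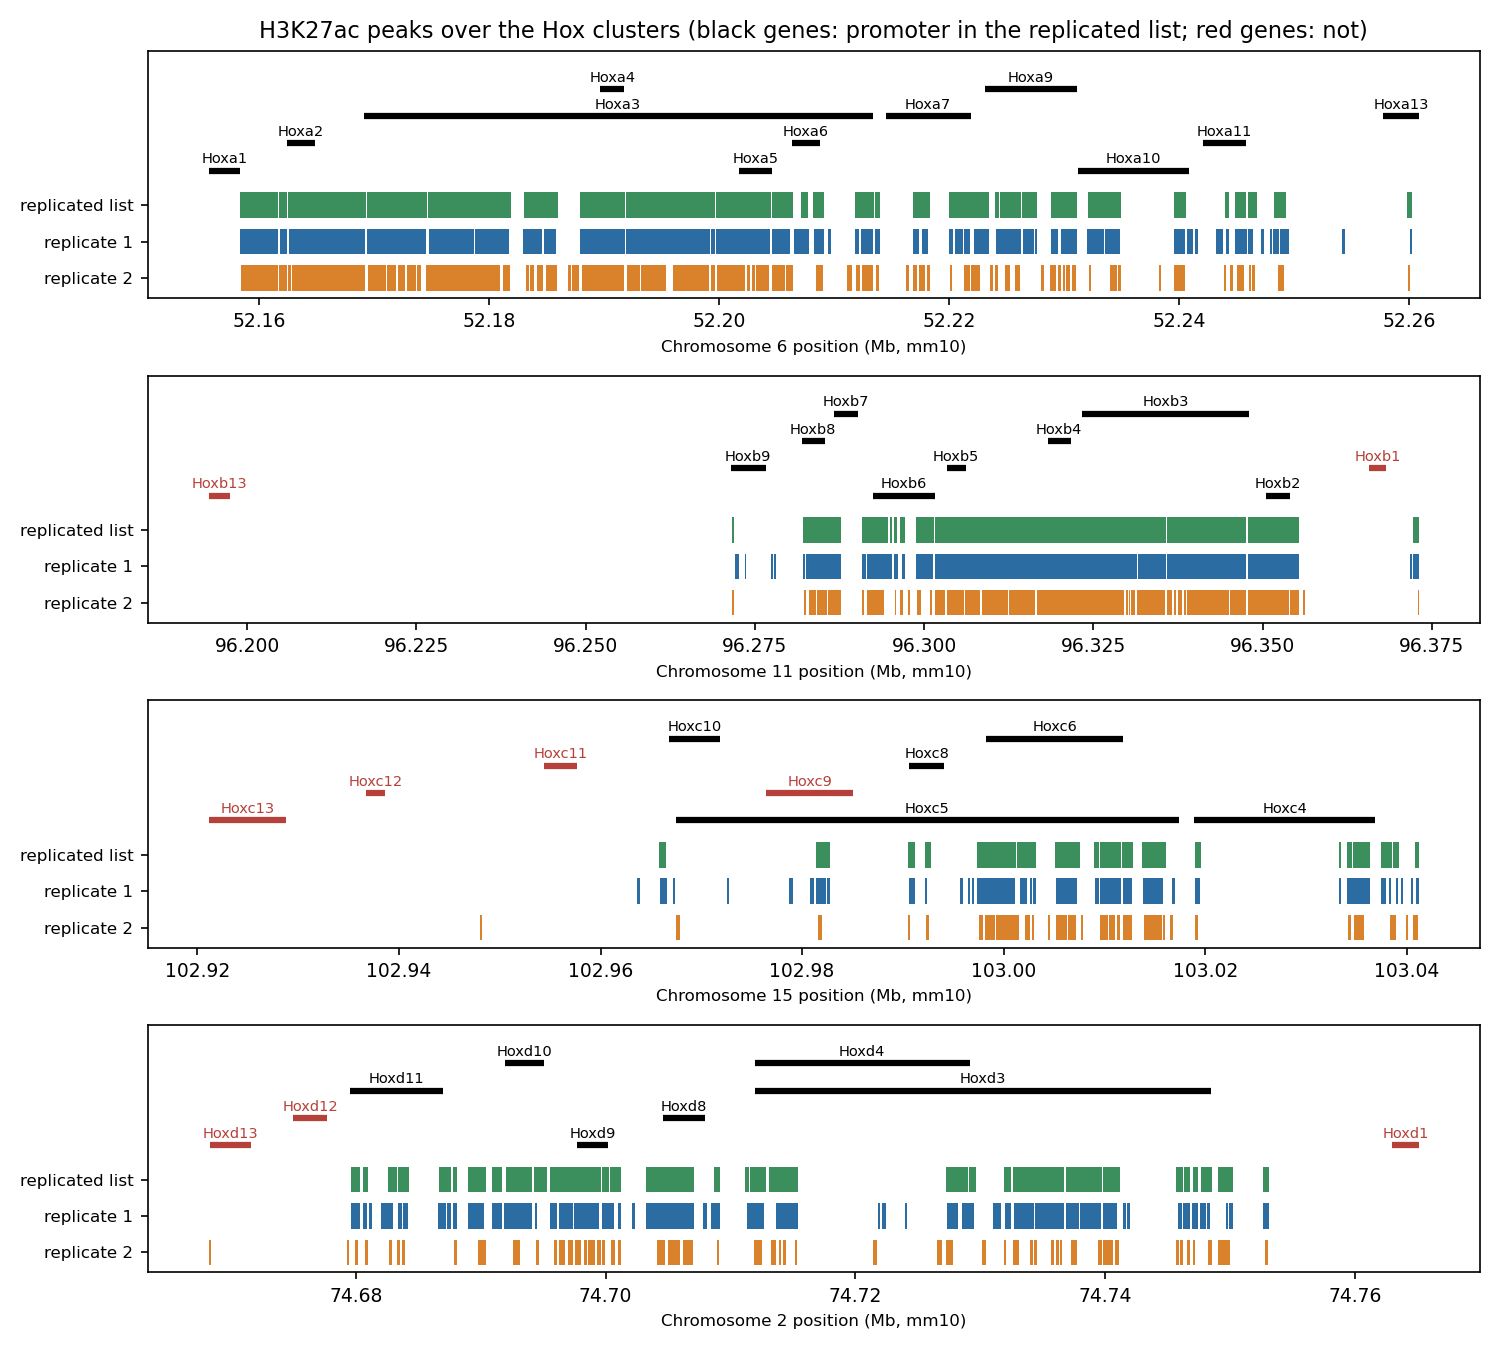
Peaks of the replicated list and of each replicate (bars) along the 4 Hox clusters, with position in Mb on mm10 and the Hox genes above; genes in red have no replicated peak at the promoter. Peaks cover 62.8% of Hoxa and 17.7% of Hoxc, and leave Hoxb13, Hoxc11 to Hoxc13, Hoxd12 and Hoxd13 unmarked, as well as Hoxb1 and Hoxd1 at the 3' ends and Hoxc9.

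Joined over gaps of up to 10 kb, the 27701 distal peaks formed 14652 stitched regions, of which 8705 held 1 peak and 148 held 10 or more. The top 100 regions carried 12.8% of the summed signal. The first was a stretch of 137354 bp with 32 peaks over Cstad on chromosome 2 (30589070 to 30726423). The second held 60 peaks over Rad51b on chromosome 12 (79804380 to 80023983), 89010 bp from the TSS of Zfp36l1. The third, on chromosome 18 (61632070 to 61695007), held Carmn and the microRNA genes Mir143 and Mir145a, which are characteristic of smooth muscle, and also the coding gene Il17b. Peaks at promoters of such noncoding genes are part of these regions. Its widest peak, 20568 bp in the replicated list, had a fold enrichment of 26.3, and the region had rank 3 in each replicate. The fourth spanned Lsp1, Tnnt3, Mrpl23 and the imprinted noncoding gene H19 on chromosome 7 (142492535 to 142612683) with 40 peaks, and its peaks also count toward Mrpl23 and the skeletal muscle gene Tnnt3 (24 distal peaks).

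The fifth region lay over Ddc on chromosome 11 (11820433 to 11903330). The sixth lay in Dnm3 on chromosome 1 (162136379 to 162226291) and held Dnm3os, the host transcript of Mir199a-2 and Mir214. The seventh (chromosome 7, 73578797 to 73619692) was 37051 bp from the TSS of Chd2, the eighth (chromosome 12, 109397503 to 109456982) held Dlk1, the ninth (chromosome 11, 120183387 to 120266639) Bahcc1, and the tenth (chromosome 1, 86433465 to 86448764) lay 7136 bp from the TSS of Tex44. Ranked by the replicates' own peaks, 9 of these 10 were in the top 10 of replicate 1 and 8 in that of replicate 2, with lowest ranks of 11 and 15. Of the top 100, 86 and 79 were in the top 100 of the respective replicate. These ranks score the same regions, stitched from the replicated list, with each replicate's peaks. That list was derived from both replicates, so part of this agreement is built in.

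**Figure D4:**
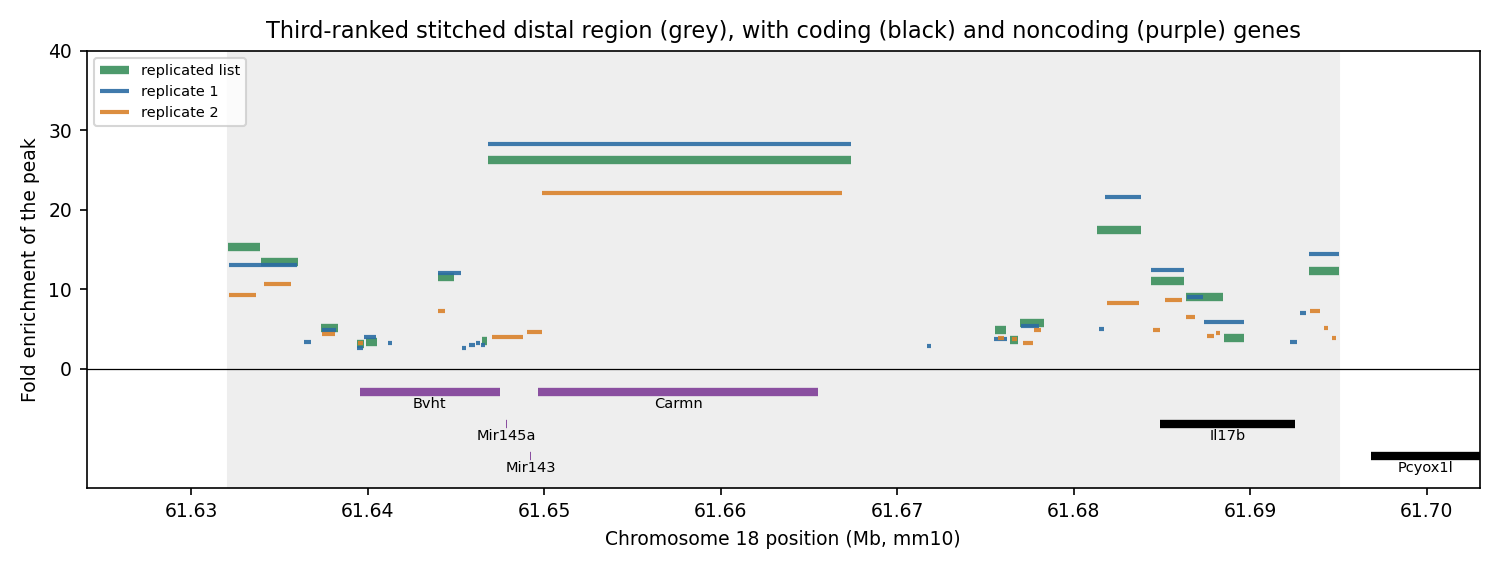
Fold enrichment (authors' values, each within its own list) and position (Mb, mm10) of all peaks in the stitched region of rank 3, shaded grey, with coding genes in black and noncoding genes in purple; each horizontal bar is 1 peak. The widest replicated peak, 20568 bp at a fold enrichment of 26.3, lies over Carmn, Mir143 and Mir145a.

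MEF2 and FOXA motifs had the highest ratios in distal peaks. MEF2 sites, bound by muscle regulators, were 2.42 times as dense as in matched controls (range over 100 control sets 1.96 to 3.02), FOXA sites 1.61 times (1.53 to 1.68), the CArG box of serum response factor 1.34 times (1.25 to 1.43), ETS sites 1.33 times and SOX sites 1.29 times. AP-1 (1.19), TCF/LEF (1.15), HNF4 (1.14), GATA (1.11), TEAD (1.11), CDX (1.09) and FOXF (1.09) sites were denser by less. These 12 of 15 motifs exceeded all 100 control sets, in each replicate's own list too, with ratios in replicates 1 and 2 of 2.18 and 2.34 for MEF2 and 1.54 and 1.58 for FOXA. CTCF sites (0.830) and E-boxes (0.936) were sparser than in all control sets, and PHOX2 sites (50 in all, ratio 0.815) lay within the control range. Of the 3 reversed sequences, which no factor is meant to bind, reversed HNF4 gave 0.952, reversed CDX 1.02 and reversed AP-1 1.07, and reversed AP-1 also exceeded all 100 control sets and reversed HNF4 also lay below all of them, in each replicate too. The E-box ratio is thus not told from sequence background. The reversed AP-1 ratio reached 1.09 in replicate 2 and 1.10 within 200 bp of the summit, so exceeding all control sets does not tell the weakest motifs, CDX, FOXF and TEAD, from sequence background, and GATA lay little above it. The FOXF consensus also takes in every FOXA site. MEF2 sites were present in 1.70% of peaks (controls 0.714%), FOXA sites in 14.2% (9.14%) and HNF4 sites in 24.9% (22.1%).

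**Figure D5:**
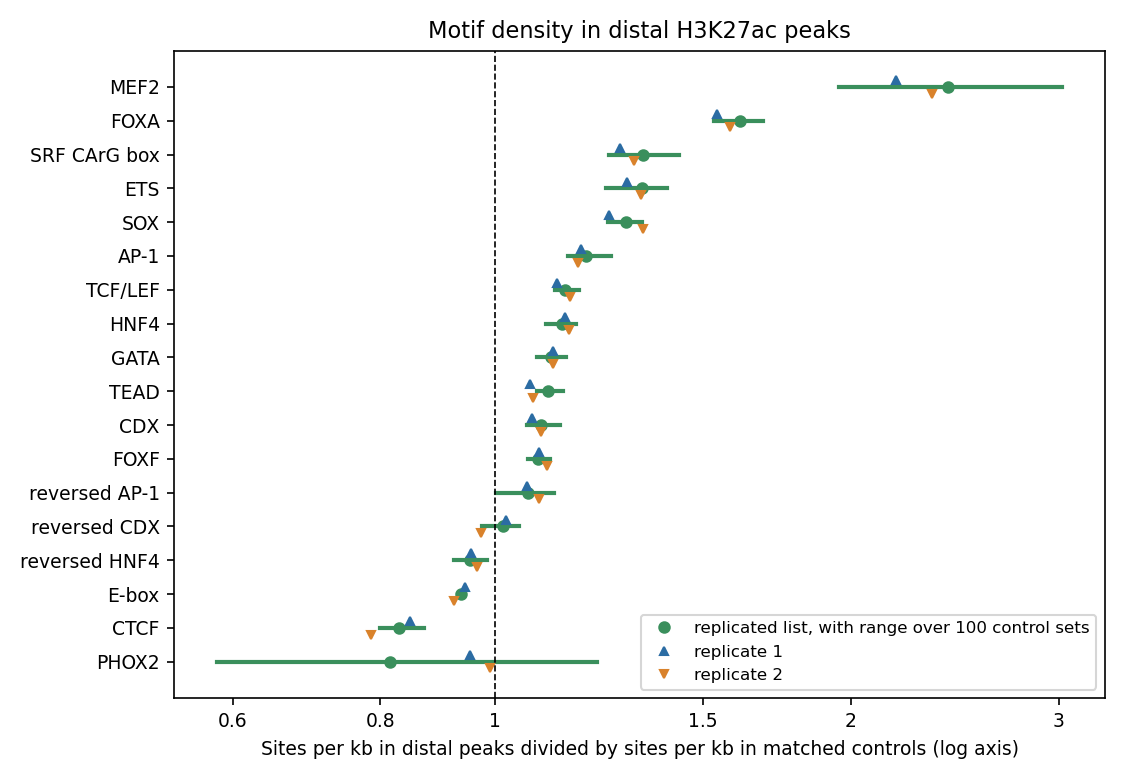
Density of each motif in distal peaks divided by its density in matched control windows (log axis); circles give the replicated list with the range over 100 control sets, triangles each replicate's own list, and the dashed line equal density. MEF2 (2.42) and FOXA (1.61) lie furthest to the right and the reversed sequences between 0.952 and 1.07.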

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

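Of the alternatives, only the restriction to replicated peaks that overlap a peak of both replicates was chosen after seeing the data. Of 761 values under an alternative, 711 were the same (same side of the test's threshold, or within the spread between replicates or 1.5 times for counts), 15 no longer passed, 17 newly passed, 18 moved and 0 reversed. For shares, that spread comes from the difference between the 2 replicates. The more they disagree, as in peak overlap (42.9 and 75.5%), the more easily a share counts as the same. With a fold enrichment of 4 or more the lists held 36938 (replicate 1), 24701 (replicate 2) and 30222 (pooled) peaks, 96.0% of the pooled peaks were in the replicated list, the promoter share was 39.1% and the intergenic share 27.7%; the filter removes weak peaks by construction. The pooled list had a promoter share of 20.6%, an intergenic share of 33.4% and 24256 stitched regions, and 35.6% of replicate 2 peaks were shared where 50% of both lengths had to overlap. In leave-one-out runs, which used 1 replicate's own list, the promoter share ranged from 21 to 28.3%, the intergenic share from 30.6 to 33.4%, lists with lower promoter marking from 6 to 10 (11 in the replicated list), stitched regions from 17907 to 25571, and covered shares from 51.4 to 62.6% (Hoxa), 34.4 to 38.8% (Hoxb), 12.9 to 18% (Hoxc) and 19.0 to 38.2% (Hoxd); the cause was not tested. Promoter marking had the same call in 232 of 253 cases, distal counts in 266 of 276, as did all but 1 of 108 motif ratios. The mesenchyme, smooth muscle, general epithelium, housekeeping, stomach, central nervous system, heart and silent lists had the same promoter call under all 11 alternatives, and liver under 7. With only peaks that overlap both replicates, enterocyte marking was 11.1% and below other genes. At least 7 of the top 10 stitched regions stayed in the top 10 under every alternative run. Read depth is unknown, so an unmarked promoter is one with no peak at the authors' threshold, not one shown to lack the mark.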

Other observations

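Some stitched regions ranked below the tenth, picked after their values were seen, lay over known noncoding or developmental genes, with no test. The thirteenth (chromosome 17, 12722473 to 12810695, 22 peaks) lay over Igf2r and its noncoding antisense gene Airn, and ranked 12 in replicate 1 and 10 in replicate 2. The eleventh (chromosome 19, 5793778 to 5824170) held the noncoding gene Malat1, and the fourteenth (chromosome 8, 84180631 to 84208661) held Mir23a and overlapped Nanos3. The fifteenth overlapped Meis1 (chromosome 11, 18866015 to 18899779, 10 peaks), a partner of Hox proteins, and ranked 20 and 12.

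Explanations were weighed for 3 patterns in which the replicates differ. The test by quintile, whose outcome follows from the overlap by strength, and both tests against matched genes were chosen only after the counts were seen. The 23 lists were compared in both directions, at promoters and distal peaks, and the enterocyte and pancreas lists were picked for their differences. With 1 group, no biological explanation was tested other than the tissue makeup of the pools.

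Replicate 1 listed more peaks than replicate 2. Background calls spread evenly over the genome, as the only source of its 49194 unshared peaks, are argued against. Of these peaks 54.0% lay within 5 kb of a replicate 2 peak, against 12.4% (highest 12.8%) for random placement. Background calls that gather near enriched regions would also lie close to replicate 2 peaks, so the placements cannot decide about them. A lower sensitivity of replicate 2 stays open: 5.29% of replicate 1's strongest quintile lacked a replicate 2 peak, against 82.9% of the weakest, but weak background calls in replicate 1 would give the same order, so these shares do not favour it. Read depth, antibody yield and the control could not be examined.

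More enterocyte promoters were marked in replicate 1 (10) than in replicate 2 (2). For weak marking near the calling limit, 8 were marked in replicate 1 alone where matched genes gave 3.93 on average (central 95% of draws 1 to 7, permutation p 0.00232), but the adjusted permutation p of 0.0534 misses the threshold, so this explanation stays open. More epithelial cells in the pool of replicate 1 could raise such calls. Near the 4 epithelial lists 58.3% of replicate 1's distal peaks lacked a replicate 2 peak, against 63.9% from their fold enrichment and below random lists, which had been set as the bound against this explanation, yet smooth muscle lay below random lists too (56.1% against 61.3%), so the bound does not single out epithelium and decides nothing. A difference in villus maturation between the pools was not tested.

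Pancreas promoters went the other way, with 3 marked in replicate 2 alone, Bhlha15, Nkx6-1 and, named after its value was seen, Rbpjl. For weak marking near the calling limit, matched genes gave 0.544 on average against these 3 (central 95% of draws 0 to 2, permutation p 0.0111), and the adjusted permutation p of 0.128 leaves this open. Pancreas tissue in the pool of replicate 2 could add such peaks, but 27.2% of 81 distal peaks near pancreas genes lacked a replicate 1 peak, against 29.6% from their fold enrichment (permutation p 0.576), inside the range of random lists, which neither shows nor excludes it. In the other direction 53.1% of replicate 1's distal peaks near pancreas genes lacked a replicate 2 peak, against 65% from their fold enrichment (permutation adjusted p 0.0274), but endoderm factors, smooth muscle and signalling genes lay below random lists too, so this does not single out pancreas. Pancreas genes also had more replicate 1 distal peaks than other genes, a mean of 6.28 against 4.05. The random lists were not matched for this, so the p-value cannot separate the share from the number of peaks.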
